A study of Homo sapiens with 8 samples.

How the data were processed

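RNA was measured in 8 libraries of MonoMac 6, an established human line derived from acute monocytic leukaemia. The labels put 4 libraries in a control group and 4 in a group that received the cytokine APRIL, the product of TNFSF13, at 100 ng/mL for 24 h. Per the labels' protocols, RNA was taken with a small-scale silica column kit and libraries were made with the Illumina TruSeq RNA v2 kit, which selects polyadenylated RNA and does not mark the strand, so reads of overlapping or antisense genes cannot be told apart. The labels describe the medium of the treated cells as free of serum and do not give the serum content of the control medium, so a difference in serum between the groups is not excluded. The growth protocol gives 10% serum for the cultures and does not say whether control cells stayed in it, and the series text puts unnamed baseline cytokines in the medium of both groups. The labels number the libraries and do not say whether they came from separate cultures. Every p-value therefore measures the spread between these libraries, which may be technical.

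The authors deposited 1 table of 11530 genes. Per the file headers, the authors deposited for each gene a value per library after scaling by a TMM factor (trimmed mean of M values), and the values run from -4.96 to 15.4, which makes them log2 values. Per the file headers, the authors also deposited a p-value and a linear fold for APRIL against control. The deposited p-value was missing for 4 genes. Recomputed from the 8 log2 values, an equal-variance two-sided test gave the deposited p-values to within 8.8e-06, and the deposited fold was 2 to the power of the difference of the group means. Per the submitters' processing notes, TopHat2 2.0.13 and bcl2fastq were used and the genome build was hg19. The read counter, the gene annotation and any filter on genes are not given in the sources used here. The symbols of 11 genes had been turned into dates, and these genes entered the tests without being named. The headers of the per-library columns give the group and no replicate number, so the libraries are called APRIL column 1 to 4 and control column 1 to 4 by their order in the table, which carries no other meaning. All 8 columns of per-library values were used.

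The depth was recovered from the values. A gene counted as recovered when its 8 values were all log2 of whole reads plus 0.5 over 1 whole-number divisor, plus a constant per library, with a chance expectation under 0.001. Whole reads were recovered for 11175 of 11530 genes (96.9%), and for 1 of 500 genes when the constants were moved. On data simulated from the reads and divisors of the 11175 recovered genes, 99.99% were resolved, and 99.9% of these had every read count right. That check covers genes already recovered and says nothing about the 355 that were not. The divisor did not track gene length (Spearman's rho = -0.0058 over 10701 genes, which are not independent replicates), with a median of 988 against a median longest transcript of 3626 bases. Changes are therefore read between libraries within a gene, and levels are not interpreted between genes. The floor on low values and the intensity trend of the fit below still use deposited levels across genes, which the divisor shifts. The recovered reads were used for the depth and for alternatives with voom.

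The test of each gene was limma 3.58.1 in R 4.3.3, with an intensity trend and robust empirical Bayes, on the log2 values as deposited and with the group as the only term. It was two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes at a linear value of 1 or more in at least 4 libraries were tested, which kept 11257 genes and left out 273. On simulated data for 11257 genes with independent noise, 200 of them changed, this fit recovered 66% of the changes of 1 log2 unit and 97% of those of 2 log2 units, and 7.39% of its calls were false. Genes of the real libraries were correlated, with an estimate of 0.89 among the ribosomal protein genes, so these shares need not carry over. The design written before the data were examined foresaw this fit for log2 values.

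The 37 gene lists of pathways, complexes and cell type markers were written before the data were examined. Lists with at least 5 tested members (33 of 37) were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Alternatives were camera with an estimated correlation and the rotation test fry. The mean deviation of each list per library was also compared by an exact two-sided permutation test over the 70 relabelings of the 8 libraries, whose smallest p is 0.0286. This last test was added after the data were examined. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for it and for the plots.

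Named genes followed a rule written before the data were examined. It takes every tested member of the list of APRIL and BAFF ligands, receptors and proteoglycans. It then takes, per direction, 12 genes past the threshold, with places left open filled by the smallest unadjusted p. It adds 2 to 4 members with the smallest p of each list described, and the 3 genes per direction with the smallest p in the authors' deposited table. The values of 1 gene that the rule takes are not reported here. The rule did not say which lists are described. That choice was made after their results were seen, first for 11 lists and later for another 5.

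Alternatives written before the data were examined changed the pseudocount, the filter on low values, the normalization, the fit, the weighting of libraries, the set test and the threshold, and left out each library in turn. Alternatives added after seeing the data left out APRIL column 3 and control column 1 together, ran voom on the recovered reads with and without quality weights, and removed from each library a spline trend (5 degrees of freedom) with transcript length and GC content, followed by camera with the preset or an estimated correlation. Length and GC content came from the longest GENCODE transcript of each symbol and were found for 95.9% of the symbols. Pairs of libraries within a group were compared by chi-square on recovered reads and differed by 1.51 to 20.6 per degree of freedom, so no pair differed by counting noise alone and none was treated as a second deposit of another. This test takes reads as independent and cannot tell whether 2 libraries came from 1 culture.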

Results

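The data are log2 expression values of MonoMac 6 leukaemia cells after 24 h with APRIL at 100 ng/mL (4 libraries) or without it (4 libraries). APRIL is a ligand of the TNF family that binds the receptors TACI and BCMA and heparan sulfate proteoglycans. The question named by the series is how this cytokine acts on acute myeloid leukaemia cells. The recovered depth was 2900838, 5424857, 957496 and 3233532 reads in APRIL columns 1 to 4, and 2091389, 1402656, 1903776 and 3013367 reads in control columns 1 to 4. These reads are those of the 11175 recovered genes and not of the whole library. Over these genes the deepest library held 5.67 times the reads of the shallowest. The median gene had 41 reads in APRIL column 3 and 256 in APRIL column 2. A change is APRIL minus control on the log2 scale, given with its standard error from limma (4 libraries per group).

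No gene passed limma's adjusted threshold between APRIL and control (1344 had an unadjusted p under 0.05), and 4 of 33 gene lists passed camera's, all higher with APRIL. None of the 4 calls held with an estimated inter-gene correlation (smallest adjusted p = 0.613). The 4 lists were the cytosolic ribosomal proteins (median change +0.41), the respiratory chain genes (+0.39), the myeloid granule genes (+0.37) and the autophagy and lysosome genes (+0.18). Without APRIL column 3 these median changes were +0.14, +0.11, +0.21 and +0.12. The largest changes among the named genes were in copies of 7SL RNA, the RNA of the signal recognition particle, at +2.87 ± 0.59 for RN7SL4P, which did not pass the threshold.

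By gene, limma called 0 genes higher and 0 lower among 11257, with a smallest adjusted p of 0.3999. At an unadjusted p under 0.05 there were 1344 genes, 704 higher and 640 lower, where chance gives 563. Without control column 1 that number was 507, without APRIL column 4 it was 669, without control column 3 it was 813 and without APRIL column 2 it was 2247. The 4 APRIL values lay wholly above the 4 control values for 407 genes and wholly below for 472, together 7.81% of genes, where chance gives 2.86%. Genes were correlated, so both chance values are averages that a single grouping of the libraries can exceed. The share without overlap was not computed for other groupings, so chance is not excluded. With library quality weights limma called 3 genes higher (EMC9, RN7SL2 and RN7SL4P) and 1 lower. These weights were 0.117 for APRIL column 3, 0.316 for control column 1 and 5.46 for APRIL column 1, so APRIL column 3 counted least. That library had RN7SL4P at 6.93, below control column 3 at 7.05. Voom on the recovered reads called 0 genes, and voom with quality weights called 1, RN7SL3, which is named for that count. Both voom fits covered the 11175 recovered genes, which held 71 of the 82 named genes. Without APRIL column 3 and control column 1 together, 0 genes were called and 846 had an unadjusted p under 0.05. With each library's trend with transcript length and GC content removed, 0 of 10809 genes were called. In that fit 893 had an unadjusted p under 0.05, 433 higher and 460 lower. The median 95% half-width of a change was 0.41.

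Among the ligands, receptors and proteoglycans of the APRIL and BAFF system, 7 genes were tested and 0 passed in limma, over all genes or adjusted over the list alone, with 1 at an unadjusted p under 0.05. The largest changes were in TNFRSF12A, the receptor of the related ligand TWEAK, at +0.64 ± 0.34 (adjusted p = 0.4003), and in GPC1, a cell surface heparan sulfate proteoglycan. TNFRSF12A lay near the floor on low values, a log2 value of 0, at 0.14 ± 0.29 (SD, n = 4) in control. It stood at 0.27, 0.23, 1.75 and 0.88 in APRIL columns 1 to 4. GPC1 stood at 5.58 ± 0.29 (SD, n = 4) with APRIL and 4.94 ± 0.32 in control, a change of +0.64 ± 0.20. TNFSF13B, which encodes BAFF, changed by +0.30 ± 0.20, and TNFSF13, which encodes APRIL itself, by +0.24 ± 0.21. The syndecans SDC2 and SDC4 gave +0.15 ± 0.18 and -0.05 ± 0.15, and the basement membrane proteoglycan HSPG2 gave -0.04 ± 0.30. TNFRSF12A was at +0.32, TNFSF13B at +0.17, TNFSF13 at +0.12 and SDC2 at -0.014 without APRIL column 3. Leaving out each library gave -0.14 to 0.038 for SDC4 and -0.23 to 0.18 for HSPG2, and SDC2 was at +0.09 without control column 4 and TNFSF13 at +0.13 without control column 1. With quality weights TNFRSF12A was at +0.11. With each library's trend with transcript length and GC content removed TNFRSF12A was at +0.19, GPC1 at +0.33, TNFSF13 at -0.0095 and SDC2 at +0.25. The list as a whole gave an adjusted p of 0.169. The deposited table held 7 of the 13 members of this list, and TACI, BCMA and the BAFF receptor were not among them. Their levels in these cells therefore cannot be judged, and why they are missing is not known.

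Of the 31 tested NF-kB target genes, which report the pathway downstream of most TNF family receptors, 18 had a positive and 13 a negative change (median +0.11, adjusted p = 0.179). The median was +0.041 without control column 3, +0.16 without APRIL column 4 and +0.025 with each library's trend with transcript length and GC content removed. By fry the NF-kB list gave an adjusted p of 0.0951 (direction higher), the smallest of any list with that test. None of the 31 genes passed in limma, over all genes or adjusted over the list alone, and 4 had an unadjusted p under 0.05. PLAUR, the urokinase receptor, changed by +0.54 ± 0.16 and NINJ1, a membrane adhesion protein, by +0.52 ± 0.21. CYLD, a deubiquitinase that restrains NF-kB signalling, changed by -0.63 ± 0.24. For each of these 3 genes the APRIL values lay wholly on one side of the control values. Among 10 survival genes of the BCL2 and IAP families, 4 changes were positive and 6 negative (median -0.08, adjusted p = 0.392). The median was -0.14 without APRIL column 3, -0.14 without control column 4 and -0.03 with the trends removed. BCL2L2 changed by -0.42 ± 0.19 and BCL2 by -0.22 ± 0.13. BCL2L2 was at -0.24 and CYLD at -0.39 without APRIL column 3. After removal of the trends PLAUR was at +0.25, NINJ1 at +0.25, CYLD at -0.33 and BCL2 at -0.0056.

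The cytosolic ribosomal protein list rose with APRIL by camera (adjusted p = 7.3e-12, and adjusted p = 0.613 with an estimated correlation), with a positive change in 74 of 77 members. In limma 0 members passed over all genes or adjusted over the list alone, and 19 had an unadjusted p under 0.05. RPLP1, RPLP2 and RPS26 changed by +0.80 ± 0.26, +0.69 ± 0.23 and +0.60 ± 0.19. The respiratory chain list rose as well (adjusted p = 3.2e-10, and adjusted p = 0.613 with an estimated correlation), with a positive change in 65 of 68 members. Here 0 members passed over all genes or adjusted over the list alone, and 11 had an unadjusted p under 0.05. ATP5D, a subunit of ATP synthase, changed by +1.04 ± 0.38, and the complex I subunits NDUFS8 and NDUFV1 by +0.54 ± 0.21 and +0.51 ± 0.18. In both lists APRIL column 3 was the highest library. The mean deviation of the ribosomal proteins was +1.01 in APRIL column 3, -0.21 to 0.03 in the other APRIL libraries and -0.33 to -0.12 in control. In the respiratory chain list APRIL column 3 stood at +1.03. Without that library the median change went from 0.41 to 0.14 in the ribosomal proteins and from 0.39 to 0.11 in the respiratory chain, with an exact two-sided permutation p of 0.171 for either list mean. RPLP1, RPLP2, ATP5D and NDUFS8 were then at +0.51, +0.45, +0.65 and +0.36. With each library's trend with transcript length and GC content removed the medians were 0.25 and 0.26, and RPLP2 was at +0.18, RPS26 at +0.39, ATP5D at +0.57 and NDUFV1 at +0.26. Over all 8 libraries as deposited the exact two-sided permutation p of either list mean was 0.0857, adjusted 0.236 over 33 lists.

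Myeloid granule genes, which encode proteases and other granule contents, had a positive change in 8 of 8 members (adjusted p = 0.0066, and adjusted p = 0.613 with an estimated correlation). None of the 8 passed, over all genes or adjusted over the list alone, and 4 had an unadjusted p under 0.05. CFD changed by +0.93 ± 0.32, neutrophil elastase (ELANE) by +0.73 ± 0.25, proteinase 3 (PRTN3) by +0.58 ± 0.24 and azurocidin (AZU1) by +0.49 ± 0.21. Autophagy and lysosome genes had a positive change in 23 of 29 members (adjusted p = 0.014, and adjusted p = 0.613 with an estimated correlation), and again 0 passed by either count, with 4 at an unadjusted p under 0.05. WIPI1, an early autophagosome protein, changed by +0.61 ± 0.25, the protease CTSD by +0.40 ± 0.17, the cargo receptor SQSTM1 by +0.28 ± 0.12 and PSAP by +0.24 ± 0.11. With each library's trend with transcript length and GC content removed, neither call held. The adjusted p became 0.858 for the granule genes, whose median change went from 0.37 to -0.01, and 0.316 for the lysosome genes, whose median went from 0.18 to 0.07. Then CFD was at +0.38, ELANE at +0.12, PRTN3 at -0.010 and AZU1 at +0.049, and CTSD was at +0.0039, SQSTM1 at +0.10 and PSAP at +0.12. The medians were 0.21 for the granule genes and 0.12 for the lysosome genes without APRIL column 3, and AZU1 was then at +0.28. CTSD was at +0.26 without control column 1 and WIPI1 at +0.38 without control column 4. Without APRIL column 3 and control column 1 the adjusted p was 0.113 for both, and without control column 1 alone the lysosome list gave 0.0554. Over all camera fits with the preset correlation the adjusted p ran from 0.0031 to 0.858 for the granule genes and from 0.0110 to 0.316 for the lysosome genes.

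**Figure D1:**
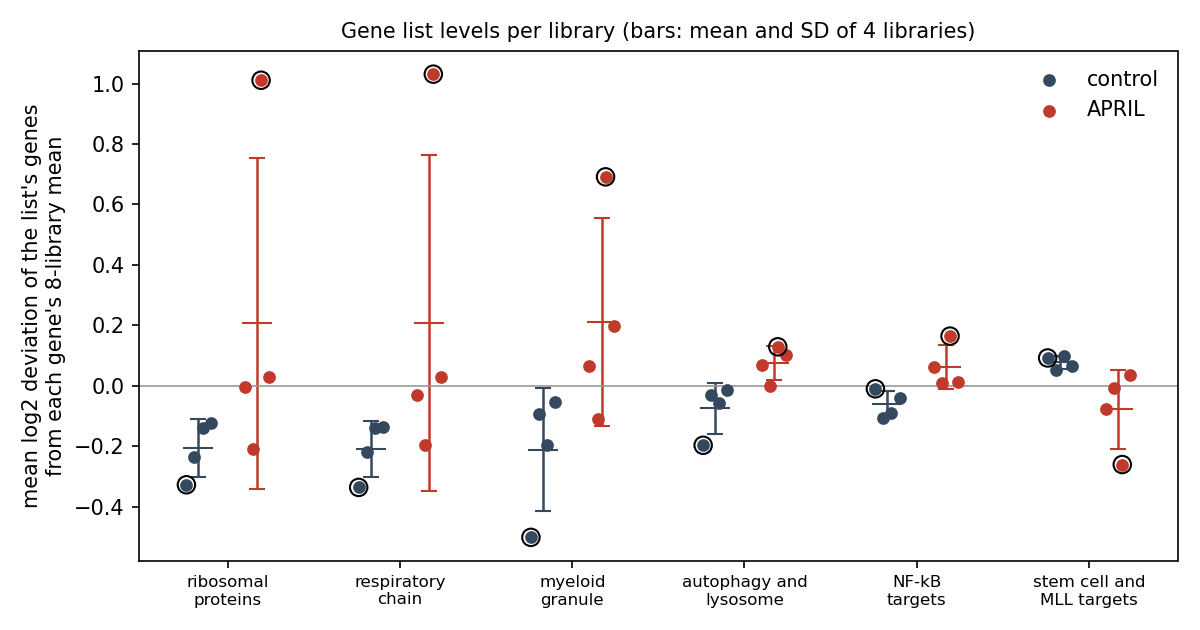
Mean log2 deviation of the genes of 6 lists from each gene's mean over the 8 libraries (vertical axis), with 1 point per library, control in blue-grey and APRIL in red, and bars for the mean and SD of 4 libraries. Ringed points are APRIL column 3 and control column 1, and APRIL column 3 stands at +1.01 in the ribosomal proteins and +1.03 in the respiratory chain.

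Genes of the stem cell and MLL-fusion programme had a negative change in 15 of 20 members (median -0.17) and missed the threshold (adjusted p = 0.0542). MEIS1, a homeobox partner of the HOXA proteins, changed by -0.31 ± 0.11, RUNX1 by -0.26 ± 0.12 and JMJD1C by -0.51 ± 0.23. Without APRIL column 4 the list gave an adjusted p of 0.0193, and with the trends with length and GC content removed it gave 0.435, the ends of its range over camera fits with the preset correlation. It also passed with the stricter filter (0.0401) and with quality weights (0.0459), and gave 0.613 with an estimated correlation. With the trends removed its median was -0.081 and MEIS1 was at -0.12, RUNX1 at -0.065 and JMJD1C at -0.21, and JMJD1C was at -0.33 without APRIL column 3. FOXO target and growth factor withdrawal genes had a negative change in 13 of 19 members (median -0.15, adjusted p = 0.169), with SESN3 at -0.60 ± 0.24 and ARRDC4 at -0.38 ± 0.15. That median was -0.094 without APRIL column 1 and -0.014 with the trends removed, where SESN3 was at -0.28. Mitosis genes had a negative change in 21 of 35 members (median -0.15, adjusted p = 0.221), with MKI67 at -0.62 ± 0.26 and TOP2A at -0.44 ± 0.19. The median was -0.08, MKI67 -0.36 and TOP2A -0.29 without APRIL column 3, without control column 1 the median was -0.10, and without both libraries it was -0.033. MKI67 was at -0.37 and TOP2A at -0.20 with the trends removed. Monocyte and macrophage genes were divided, 14 positive and 11 negative (median +0.03, adjusted p = 0.823), and the median was -0.018 without APRIL column 1, +0.10 without APRIL column 2, +0.0099 without control column 1 and -0.036 with the trends removed. In that list the endotoxin receptor TLR4 changed by -0.43 ± 0.17, versican (VCAN) by -0.50 ± 0.20 and the transcription factor CEBPD by +0.49 ± 0.21, and VCAN was at -0.32 without APRIL column 3. CEBPD turned to -0.022 with the trends removed, where TLR4 was at -0.092 and VCAN at -0.20. Sterol efflux genes had a positive change in 7 of 9 members (median +0.26, adjusted p = 0.0961), with APOE at +0.69 ± 0.22 and PLTP at +0.38 ± 0.18. This list passed with the stricter filter on low values (adjusted p = 0.0194, and 0.0194 to 0.462 over camera fits with the preset correlation), gave 0.613 with an estimated correlation on the values as deposited, and had a median change of +0.09 with the trends removed, where APOE was at +0.073 and PLTP at +0.087. PLTP was at +0.23 without control column 1. In these 5 lists 0 members passed in limma over all genes or adjusted over the list alone, and 2 of the stem cell genes, 3 of the FOXO targets, 4 of the mitosis genes, 5 of the monocyte genes and 1 of the sterol efflux genes had an unadjusted p under 0.05.

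Of markers of other cell types, B cell and plasma cell markers had 7 tested members, 6 with a positive change (median +0.04, or +0.031 to +0.13 when each library was left out and -0.14 with the trends removed, adjusted p = 0.562). T cell and NK cell markers had 2 tested members, erythroid markers 1, fibroblast, epithelial and endothelial markers 1 and mitochondrially encoded genes 0, too few for a test. Over the 29 tested lists that did not pass, the smallest adjusted p was that of the stem cell genes.

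The 12 genes with the smallest p in each direction filled the places of the rule, since none passed (adjusted p = 0.3999). Higher with APRIL were SLC2A8, a glucose transporter, at +1.31 ± 0.29, B9D2, a protein of the ciliary transition zone, at +1.03 ± 0.22, and PPP1R16A, a regulatory subunit of protein phosphatase, at +0.86 ± 0.17. TSTD1, NPDC1, PINK1, EMC9 and ICAM5 followed at +0.72 to +0.85. PINK1, the kinase that marks damaged mitochondria, stood at 2.07 ± 0.11 (SD, n = 4) with APRIL and 1.29 ± 0.29 in control. Lower with APRIL were CEP85L, a centrosomal protein, at -1.19 ± 0.31, the phosphatase PPM1E at -1.03 ± 0.27 and UACA at -0.83 ± 0.20. ZNF107, WDR52, FILIP1L, ALG11, SP110 and ZNF507 ranged from -0.73 to -0.52. With the length and GC trends removed B9D2 was at +0.54, TSTD1 at +0.36, NPDC1 at +0.43, EMC9 at +0.26 and ICAM5 at +0.35. Among the lower genes ZNF107 was at -0.47, WDR52 at -0.47, ZNF507 at -0.24 and HSPE1P2 at -0.71. HAUS6P1 (-0.80 ± 0.16) and HSPE1P2 (-0.47 ± 0.12) are pseudogenes whose reads can come from near-identical genes, so their values are uncertain.

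The remaining places went to 4 copies of 7SL RNA. With RN7SL3 they made 5 genes, whose mean level was 8.51 ± 0.81 (SD, n = 4) with APRIL and 5.94 ± 1.32 in control, a 5.95-fold difference with an exact two-sided permutation p of 0.0571. The changes of RN7SL1 and RN7SL5P were +2.59 ± 0.62 and +2.40 ± 0.60. RN7SL4P had 3671, 5645, 296 and 3213 recovered reads in APRIL columns 1 to 4 and 117, 93, 712 and 338 in control columns 1 to 4. These copies are near-identical and can share reads, so they are not counted as separate genes. 7SL RNA carries no poly(A) tail, and the kit selects polyadenylated RNA.

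**Figure D2:**
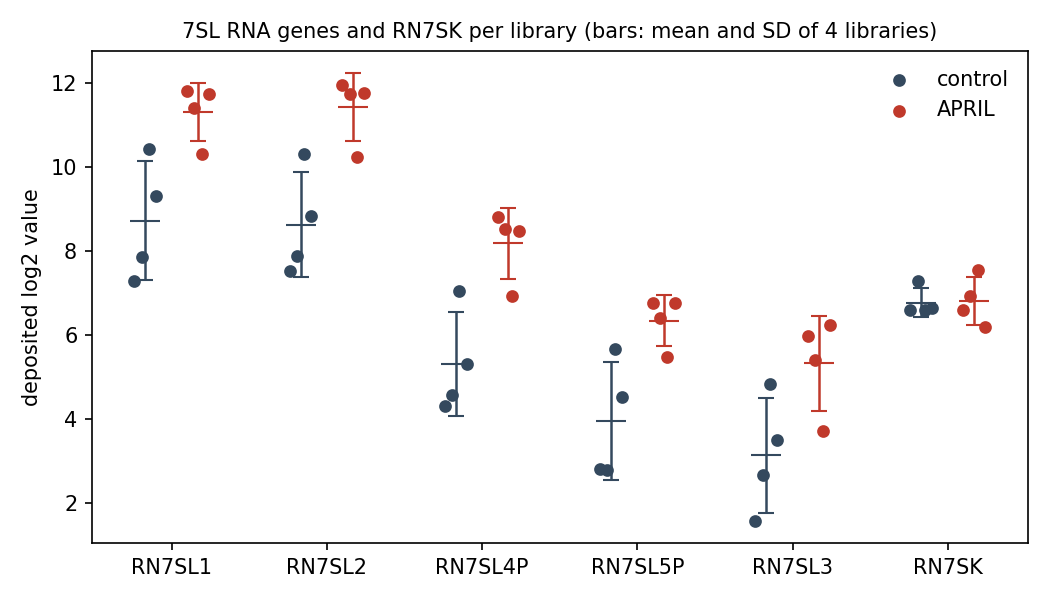
Deposited log2 values (vertical axis) of 5 copies of 7SL RNA and of RN7SK, another small RNA without a poly(A) tail, with 1 point per library, control in blue-grey and APRIL in red, and bars for the mean and SD of 4 libraries. The APRIL and control points of RN7SL4P overlap through APRIL column 3, and RN7SK changed by +0.05 ± 0.28. RMRP and RPPH1 are not shown. Over these 3 other RNAs the change ran from 0.05, that of RN7SK, to 1.14, with a median of 0.88.

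The libraries also differed in trends with transcript length and GC content. Over 10809 genes, which are not independent replicates, the change with APRIL went down with transcript length (Spearman's rho = -0.54) and up with GC content (rho = 0.51), and without APRIL column 3 and control column 1 these were -0.32 and 0.41. Compared between the groups, the trends of the 4 and 4 libraries gave an exact two-sided permutation p of 0.114 for length and 0.0857 for GC content. With these trends removed 53 of 82 named genes moved by over 1.5 times, 49 of them towards 0. Without APRIL column 3 it was 23 of 82, 21 of them towards 0. Without APRIL column 3 and control column 1 together it was 41 of 82, 40 of them towards 0. Length and GC content together accounted for 3.14% of the variance of deviations in control column 4 and 57.0% in control column 1. The median length of the longest transcript was 1857 bases for the ribosomal proteins, 1407 for the respiratory chain and 1118.5 for the granule genes. Over all tested genes it was 3630. The form that the cells express need not be the longest, so the removal of these trends may be incomplete. The trends were fitted without the group, so their removal can also take out a difference between the groups that follows length or GC content. The granule genes had a median GC content of 61.0% against 47.9% over all tested genes. The first principal component held 57.3% of the variance, with APRIL column 3 at 67.0, control column 1 at -28.2 and the other libraries from -14.4 to 7.02.

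The authors' deposited table held 982 genes at a p under 0.05, 394 higher and 588 lower, and 118 under 0.01. Benjamini-Hochberg adjustment of the p-values in the authors' deposited table left 0 genes, with a smallest adjusted value of 0.480. Both that table and limma gave an unadjusted p under 0.05 for 669 genes. The smallest p-values in the authors' deposited table were for the splicing factor LUC7L (1.18-fold), NRSN2 (1.35-fold) and SPG7 (1.21-fold) upward. Downward in the authors' deposited table they were for the TGF-beta receptor TGFBR2 (0.792-fold), the glycosylation enzyme PMM2 (0.830-fold) and RDH10 (0.820-fold). In limma the unadjusted p was 0.065 for LUC7L, 0.085 for SPG7 and 0.058 for PMM2, and under 0.05 for NRSN2, TGFBR2 and RDH10. Over the alternatives the log2 change ran from +0.15 to +0.25 for LUC7L, +0.10 to +0.46 for NRSN2 and +0.21 to +0.31 for SPG7. It ran from -0.37 to -0.23 for TGFBR2, -0.30 to -0.12 for PMM2 and -0.31 to -0.22 for RDH10.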

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

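A value of a named gene or described list was singled out when it stood apart from the other 3 libraries of its group, by a gap larger than chance gives in about 1 of 20 groups. Of 206 groups of values tested 16 had such a value, where chance gives about 10.3, and they lay in APRIL column 3 (9), control column 1 (6) and control column 3 (1). The lists described first gave 12 of 168 groups and the 5 added later, after results were seen, gave 4 of 38. Both tests of APRIL column 3 below had their bounds written before the result was seen.

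In APRIL column 3 the log2 level was 6.24 for SDC2 (others 5.53 to 5.61), 10.23 for RN7SL2 (11.74 to 11.96), 2.68 for SPG7 (2.53 to 2.54) and 3.18 for BCL2L2 (3.86 to 3.95). It was 5.35 for RPS26 (4.67 to 4.77), 12.42 for PSAP (12.19 to 12.23) and 8.03 for TPI1 (6.999 to 7.14). The mean deviation there was 0.040 for the survival genes (others -0.068 to -0.054) and -0.25 for the interferon-stimulated genes (0.041 to 0.071). In control column 1 the log2 level was 4.45 for JMJD1C (others 3.81 to 3.90) and 13.14 for ALDOA (13.49 to 13.56). The mean deviation in control column 1 was 0.15 for the FOXO target genes (0.030 to 0.043), 0.16 for the mitosis genes (-0.0069 to 0.020), -0.25 for the glycolysis genes (-0.0018 to 0.015) and -0.33 for the APRIL and BAFF list (-0.087 to -0.042). MEIS1 was at 7.45 in control column 3 (7.65 to 7.67).

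APRIL column 3 was the shallowest library, with 957496 reads, and its typical deviation was 2.61 times the median of the other libraries. Counting noise was predicted to bring this ratio to 1.5 or less in the 2794 recovered genes with the most reads, and it was 3.77 there. The 355 genes without recovered reads could not enter this set, whatever their level. Counting noise shrinks with reads in every library, so the ratio alone cannot decide. The deviation of APRIL column 3 was 0.74 over all tested genes and 0.65 over the genes with the most reads. Over the latter genes it was 0.12 to 0.42 in the other libraries. That deviation stayed high where recovered reads were most, which argues against depth as the whole cause. A trend with transcript length and GC content predicts a ratio of 1.5 or less once it is removed. The ratio was then 2.78, which argues against a trend with the length and GC content of the longest transcripts as the whole cause. A difference in RNA integrity or in the culture behind this library stays open and was not tested. The design gives no biological explanation for 1 library of a group, and none was tested.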

How the results depend on the processing

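The alternatives without APRIL column 3 and control column 1 together, with voom and with the length and GC trends removed (with either correlation) were chosen after seeing the data. Over all alternatives, the 82 named genes gave 1591 values with the same direction and side of the threshold, 4 that passed and 12 that changed sign, in 7 genes. Genes past the threshold stayed at 0 in both directions when each library was left out in turn, and the lists past it ranged from 3 to 5. Quality weights gave 3 genes higher and 1 lower, and voom with quality weights gave 1 higher. Lists past the threshold went from 4 to 6 with the stricter filter on low values, which added the sterol efflux genes (adjusted p = 0.0194) and the stem cell genes (0.0401), to 3 with quantile normalization, to 2 without APRIL column 3 and control column 1, to 2 with voom and quality weights, to 0 with an estimated correlation (also with the trends removed) and to 0 with fry, whose smallest adjusted p was 0.0951. That smallest fry value belonged to the NF-kB target genes. With the trends removed and the preset correlation 4 lists passed, of which the fatty acid and heat shock lists had not passed before. Without adjustment the authors' deposited table held 982 genes. Leaving out each library gave camera adjusted p of 1.6e-15 to 2.1e-06 for the ribosomal proteins and 1.1e-12 to 0.000339 for the respiratory chain. With the preset correlation both of these lists passed in 35 of 35 splits of the 8 libraries, so these ranges say nothing about APRIL. For the granule genes the range was 0.0031 to 0.0354, and for the lysosome genes it was 0.0110 to 0.0554.

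The values that changed sign follow. Leaving out each library gave -0.14 to 0.038 for SDC4 (highest without APRIL column 2) and -0.014 to 0.22 for SDC2 (lowest without APRIL column 3), which was -0.018 without APRIL column 3 and control column 1. It gave -0.23 to 0.18 for HSPG2, positive without APRIL column 3 (0.18), control column 2 (0.14) or control column 3 (0.035), and HSPG2 was at 0.15 with voom and 0.029 with voom and quality weights. With the length and GC trends removed TNFSF13 went from 0.24 to -0.0095, PRTN3 from 0.58 to -0.010, CEBPD from 0.49 to -0.022 and CD74 from 0.33 to -0.0094, so each lost its whole change. That loss does not show the changes to be technical, since the removal can also take out a difference between the groups. With quality weights, lowest for APRIL column 3 (0.117) and control column 1 (0.316), 38 of the 82 named genes moved by over 1.5 times. The cause was not tested. No paired analysis was possible because the columns of the deposited table carry no replicate number. The quasi-likelihood test and the size-factor Wald test were planned for the case that whole reads could be recovered, and they were recovered for 96.9% of genes. Leaving these tests out departs from the plan, since the deposited unit is log2, and voom on the recovered reads was run instead. Depth limits the shallowest library most, where the median gene had 41 reads.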

Other observations

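The 5 lists of the first 2 paragraphs (fatty acid synthesis, glycolysis, MHC class II, interferon-stimulated and adaptor genes) were chosen for description after their results were seen, as was the heat shock list, and none passed the threshold with the values as deposited. Fatty acid synthesis genes had a negative change in 12 of 14 members (median -0.16, adjusted p = 0.120 by camera), with ACACA, the rate-limiting enzyme, at -0.52 ± 0.25 and ME1 at -0.40 ± 0.14. Their median was -0.075 without APRIL column 3, with a negative change in 9 of 14 members, and ACACA was then at -0.25. With the length and GC trends removed this list passed (median -0.11, ACACA at -0.30, adjusted p = 0.0368, in a range of 0.0368 to 0.2498 over camera fits with the preset correlation), as did the heat shock genes (0.0243, in a range of 0.0243 to 0.858, and 0.392 as deposited). With the trends removed and an estimated correlation neither list passed (adjusted p = 0.644 for both). Glycolysis genes had a positive change in 15 of 21 members (median +0.22, adjusted p = 0.169), with TPI1 at +0.55 ± 0.21, ALDOC at +0.51 ± 0.19 and ALDOA at +0.40 ± 0.16. That median was +0.12 without control column 1, +0.14 without APRIL column 3 and +0.073 with the trends removed, and without APRIL column 3 TPI1 was at +0.31 and ALDOC at +0.33. TPI1 was at +0.24, ALDOC at +0.24 and ALDOA at +0.26 with the trends removed. MHC class II genes had a positive change in 5 of 6 members (median +0.33, adjusted p = 0.274), with HLA-DPA1 at +0.34 ± 0.26 and the invariant chain CD74 at +0.33 ± 0.12, which was -0.0094 with the trends removed. The list's median was +0.067 with the trends removed and +0.17 without APRIL column 3, where HLA-DPA1 was at +0.17.

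Interferon-stimulated genes went both ways, 10 positive and 15 negative of 25 (median -0.18, adjusted p = 0.523). The median was -0.051 without APRIL column 3, -0.10 without control column 1, +0.0059 without both, -0.28 without APRIL column 2 and -0.087 with the trends removed. IFI6 changed by +1.09 ± 0.36 and IRF7 by +0.71 ± 0.26, while DDX60 changed by -0.78 ± 0.28 and XAF1 by -0.48 ± 0.18, and without APRIL column 3 IFI6 was at +0.68 and DDX60 at -0.50. TNF receptor adaptors and NF-kB kinases were also divided, 11 positive and 9 negative (median +0.06, or -0.0091 without control column 4, +0.026 without APRIL column 2, +0.13 without APRIL column 3 and -0.026 with the trends removed, adjusted p = 0.628), with TRAF2 at +0.35 ± 0.16, TRAF6 at +0.35 ± 0.14 and TAB2 at -0.38 ± 0.14. IFI6 was at +0.69, IRF7 at +0.24, TRAF2 at +0.032 and TAB2 at -0.20 with the trends removed. In these 5 lists 0 members passed in limma over all genes or adjusted over the list alone, and 1 fatty acid, 5 glycolysis, 1 MHC class II, 6 interferon-stimulated and 4 adaptor genes had an unadjusted p under 0.05. The mean deviation of 6 lists, among them the NF-kB targets and the stem cell genes, reached the smallest exact permutation p that 70 relabelings can give, 0.0286, and the adjusted value over 33 lists was 0.157. With the trends removed the exact permutation p was 0.286 for the NF-kB targets and 0.114 for the stem cell genes, and of the 6 lists the lysosome genes alone stayed at 0.0286.

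The tests below were chosen after the results they measure were seen. In 35 of the 35 splits of the 8 libraries into groups of 4, the real one included, at least 0 genes passed, and the highest other count was 0, so this count says nothing against chance. The real 1344 genes at an unadjusted p under 0.05 were reached in 2 of 35 splits, with 1823 in the highest other, and chance is not excluded. The real 4 lists were reached in 9 of 35 splits, with 5 in the highest other, and chance is not excluded.

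The first pattern is the lists that rose. The ribosomal protein and respiratory chain lists were both past the threshold in 35 of 35 splits, which is consistent with libraries that differ in these lists whatever the group, and the estimated correlation between ribosomal protein genes was 0.89. Trends with length and GC content as the whole cause, or APRIL column 3 alone, cannot be told apart from a difference between the groups there, because the median changes of 0.41 and 0.39 came down to 0.25 and 0.26 with the trends removed and to 0.14 and 0.11 without that library, where the larger exact permutation p of the list means was 0.114 and 0.171. For the granule and lysosome lists the smaller camera adjusted p was 0.316 with the trends removed, so the trends may account for these calls. The mean change of the lysosome list went from 0.15 to 0.07, then with an exact permutation p of 0.0286 (adjusted 0.189). That p is the smallest that 70 relabelings can give and does not measure the size of the change. An effect of APRIL, or of a difference in serum that the labels leave open, stays untested for all 4 lists and is not separated from differences between libraries.

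The second pattern is the higher 7SL RNA with APRIL. Shared reads between copies may make 1 signal look like 5 genes, since the lowest correlation between copies over the 8 libraries was 0.957. A general rise in RNA without a poly(A) tail is not shown by 10 replication-dependent histone genes, most of whose messages lack the tail. Their median change was 0.21 (0.075 without APRIL column 3 and -0.079 with the length and GC trends removed) against 2.57 for 7SL. A general rise still cannot be told apart from a rise in 7SL alone. RMRP, RPPH1 and RN7SK had a median change of 0.88 with an SD of 0.57. Histone genes also have polyadenylated forms, which would hide a general rise. Chance was not excluded, with an exact permutation p of 0.0571, and a change in 7SL RNA in the cells stays open as a hypothesis.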
